A study of Rattus norvegicus with 24 samples.

How the data were processed

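Gene expression was measured with one-colour Agilent rat arrays in prostate, skin and forebrain of castrated males and in ovary of intact females, all Sprague-Dawley rats of 12 weeks, per the labels. The males had been castrated 3 days before a single intraperitoneal dose of 10 mg/kg dihydrotestosterone (DHT) or vehicle, and tissues of both sexes were taken after 16 h, per the labels' protocols. The short design text of the series speaks of castrated males for all 4 tissues. The sample labels list the ovary animals as intact females, and the sample labels were followed here. Each of the 8 groups had 3 arrays. Forebrain vehicle array 3 failed the authors' quality control, per its label, and was left out, so that 23 of the 24 arrays entered the tests. The labels do not say whether prostate, skin and forebrain of one number came from the same male, nor in words that the 3 samples of a group came from separate animals, although the design text calls them biological replicates.

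RNA was amplified and labelled with Cy3, per the labels' protocols. The deposited files held the intensity of each spot of 1 array on a linear scale, written by Agilent Feature Extraction 10.5.1.1 per the file headers, or 10.1 per the submitters' processing notes. The intensity used for the tests was the processed signal, which the scanner software had background-subtracted and spatially detrended but not normalized between arrays, per the file headers. The submitters' processing notes also name limma, with no version or model. An array had 42429 spots, of which 1417 were control spots and were left out. Spots marked as outliers were left out on their array, and no spot was saturated on any array. The 41012 remaining probes carried an accession and no gene symbol in the deposited files. A symbol was found for 10813 probes (8945 symbols) by matching the accession without its version to a table of the GRCr8 assembly, which was used for names only. The other 30199 probes were tested under their own identifier and are counted but not named. No genome positions are given, because the arrays were designed on an older assembly.

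The 6 slides held 4 arrays each, 1 of every tissue. Vehicle arrays lay on 3 slides and DHT arrays on the other 3, all scanned on 1 day. DHT and vehicle could therefore not be compared within a slide, and slide entered the fits of single genes over all tissues as a random block.

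The values tested were log2 of the processed signal minus the 75th percentile of that array. Probes were kept where they were well above background on at least 3 of the arrays fitted, and a gene with several probes was represented by the one with the highest mean signal. Levels are given on this scale, as log2 differences from the 75th percentile of the array. Each tissue was fitted alone with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors of log2 fold changes are the standard errors of limma, and errors of levels are standard deviations. A fit over 20751 genes kept in all tissues tested whether the effect of DHT differed between tissues (a moderated F test) and whether it differed from 0 on average over the 4 tissues, with slide as a random block and a correlation of 0.103 between arrays of a slide, estimated on 2000 randomly drawn genes. Where a gene was not well above background on any array of one group, its change is given as at least N-fold, from the mean of the brighter group against the mean of, per array, the higher of the probe's own signal and the lowest signal well above background.

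Before the data were examined, 37 gene lists (695 entries, 531 of them on the array) were fixed for pathways, hormone responses and cell types, together with the models, the alternatives and the rule for the genes named. Lists with at least 5 tested genes were tested with camera of limma at a preset correlation of 0.01, again with a correlation estimated from the data, and with fry. Camera asks whether a list moved against the other genes of the array. Fry asks whether the members moved, without comparison to the other genes. Calls of lists are those of camera at the preset correlation. Counts said to be adjusted over the list alone used only the members of that list for the adjustment. Tests of the difference of a list between tissues were added after the data had been seen, and used all arrays without a slide block.

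The genes named per tissue were the 10 largest rises and 10 largest falls among genes with a symbol that passed the threshold and in which every DHT array lay on one side of every vehicle array. To these came Fkbp5, Zbtb16, Sgk1, Tsc22d3, Pbsn, Clu, Odc1 and Igf1 with their values whatever the test (other genes of that set are not reported here), up to 4 members of each list with a call, the 10 genes with the smallest adjusted p for the difference between tissues, and the 10 largest rises and falls on average. Other genes named were chosen after their values had been seen, and the text says so there.

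Every model was tested on simulated data with known changes. Values were drawn around the real mean of each gene, with its residual spread on the real arrays taken as its true spread. In prostate, the fit recovered 53 of 100 genes changed 4-fold and 12 of 100 changed 2-fold among 23738 genes. In forebrain it recovered 74 and 18 of 100 among 26361 genes. In ovary (29400 genes) and skin (24122 genes) it recovered 0 of 100 at either size under these settings. This holds for the fits of ovary and skin alone, where a lack of called genes thus says little about changes of these sizes. The limma fit of all arrays is a different model. It called, for example, Prr5l in skin at a log2 fold change of -1.32 (adjusted p = 0.00643), which does not bear on the recovery of the fit of skin alone. The test of differences between tissues recovered 54 and 6 of 100, and the average over tissues recovered 97 and 69 of 100. The precision of an array study is limited by the number of arrays, here 3 per group or fewer.

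Alternatives were quantile normalization, other filters on dim probes, the mean of a gene's probes, a variance prior with trend and robust estimation, array weights, 1 fit of all arrays, the replicate number as a block, the forebrain array left out by the authors, and each array or slide left out in turn. A background correction with normexp (offset 50) was planned on the mean signal, a column that the files used here do not hold, and was run on the median signal instead. That setting, and a run without 2 ovary vehicle arrays with compressed signal, were chosen after seeing the data. The latter leaves 1 ovary vehicle array, so that its spread comes from the DHT arrays alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.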

Results

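DHT, an androgen that is not converted to estrogen, was given to castrated male rats and to intact females, and RNA of 4 androgen-exposed tissues was profiled 16 h later. The question set by the design was which genes DHT changed in prostate, ovary, skin and forebrain, and whether these responses were shared. The 24 arrays covered 8 groups of 3, from which 1 forebrain vehicle array was left out. On the 23 arrays used, 54.6% (skin vehicle array 2) to 97.0% (ovary vehicle array 3) of probes were well above background. Lists of keratinocyte and neuronal markers followed the tissue labels. Keratinocyte genes had a mean log2 level of 5.49 ± 0.42 (SD) in vehicle skin and -3.78 ± 0.59 in vehicle forebrain. Neuronal genes had one of 2.65 ± 0.12 in vehicle forebrain and -5.16 ± 0.88 in vehicle prostate. Skin also had high levels of skeletal muscle genes, with a mean of 5.45 ± 6.26 on vehicle and 9.19 ± 1.27 on DHT arrays. These genes lay far lower on skin vehicle array 1 than on the other skin arrays. The p-values measure the spread between these samples.

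**Figure D1:**
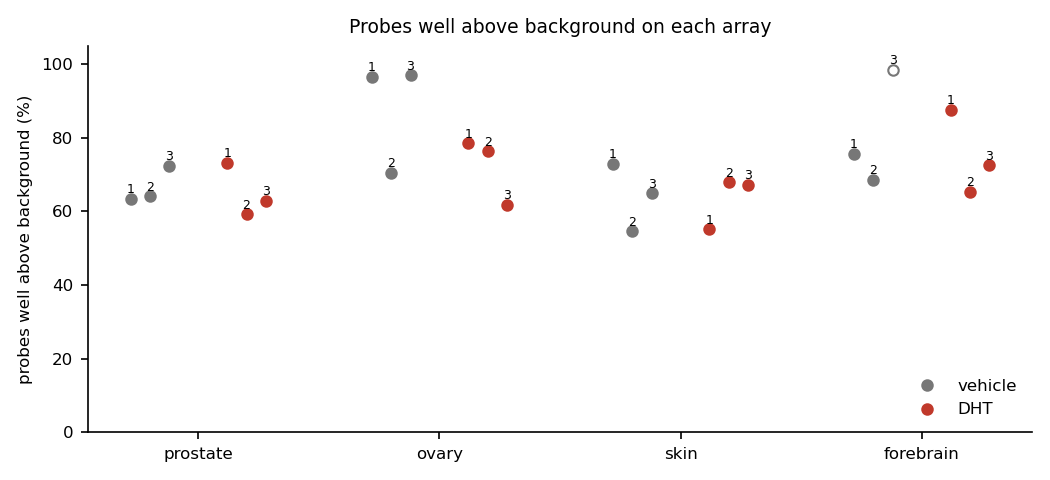
Percent of probes well above background (vertical axis) on each of the 24 arrays, by tissue and treatment, with the replicate number above each point and the array left out by the authors as an open circle. Ovary vehicle arrays 1 (96.5%) and 3 (97.0%) lay close to the array left out (98.4%), and the other arrays between 54.6% and 87.5%.

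In prostate, the largest rises with DHT included genes of secreted proteins and peptides. Pbsn, which encodes the androgen-dependent secretory protein probasin, rose 57.7-fold, from a log2 level of -3.81 ± 0.22 to 2.04 ± 0.59 (SD, n = 3 each). Creld2, a factor of the endoplasmic reticulum, rose 13.3-fold, Rln1, which encodes relaxin, 15.7-fold, and Gal, which encodes the neuropeptide galanin, 12.0-fold. The other large rises were those of Cntn6 (20.7-fold), Abo3 (17.5-fold), Trim54 (13.3-fold) and Cyp4a8 (11.2-fold). Nppc, which encodes C-type natriuretic peptide, rose at least 4.08-fold and Glyatl2 at least 2.41-fold, both from vehicle levels not well above background. Their place among the 10 largest rises is therefore not certain. Cntn6 and Cyp4a8 were well above background on 1 of 3 vehicle arrays. The adjusted p of these 10 genes lay between 0.00325 and 0.0267 (limma).

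The largest falls in prostate included chemokines and secreted peptides. Calcb, a calcitonin gene-related peptide gene, was 30.9-fold lower with DHT, and the neutrophil chemokines Cxcl1 and Cxcl2 were 18.4-fold and 9.26-fold lower. Ubd, which encodes a ubiquitin-like modifier induced by cytokines, was 18.8-fold lower, Stra6l 21.0-fold, the odorant receptor gene Or2h2c 10.4-fold, Cyp3a9 9.25-fold, the zinc transporter gene Slc30a2 8.58-fold and Sfnl1 8.05-fold (2 vehicle arrays). Bdnf, which encodes a neurotrophin, was at least 8.16-fold lower and not well above background with DHT. Stra6l, Or2h2c and Cyp3a9 were well above background on 2 of 3 DHT arrays. The adjusted p of these 10 genes lay between 0.00390 and 0.0213.

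Of the androgen-regulated genes chosen beforehand, Fkbp5, a co-chaperone of steroid receptors, rose by 2.52 ± 0.21 log2 units in prostate (SE, adjusted p = 0.00549, 2 DHT arrays), Igf1 by 1.28 ± 0.22 (adjusted p = 0.0198, with 1.21, 0.43 and 0.32 on its other probes) and Odc1, the first enzyme of polyamine synthesis, by 1.04 ± 0.18 (adjusted p = 0.0217). Zbtb16 (1.40 ± 0.39, adjusted p = 0.0765) and Tsc22d3 (1.04 ± 0.33, 0.1003) did not pass, although every DHT array lay above every vehicle array. Clu (0.79 ± 0.47, adjusted p = 0.334) and Sgk1 (0.32 ± 0.28, 0.508) did not pass either. Clu had a log2 fold change of -0.10 with quantile normalization. The list of androgen response genes did not shift as a whole (adjusted p = 0.964 with camera and 0.959 with fry). Fry for members in either direction gave an adjusted p of 8.475e-05, and most prostate lists passed that form. Among its 26 measured members 2 rose (Fkbp5 and Acsl3) and 3 fell, the stress-responsive gene Ndrg1 (-1.87) and the keratin genes Krt19 (-1.41) and Krt8 (-0.99), members named after their values had been seen.

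**Figure D2:**
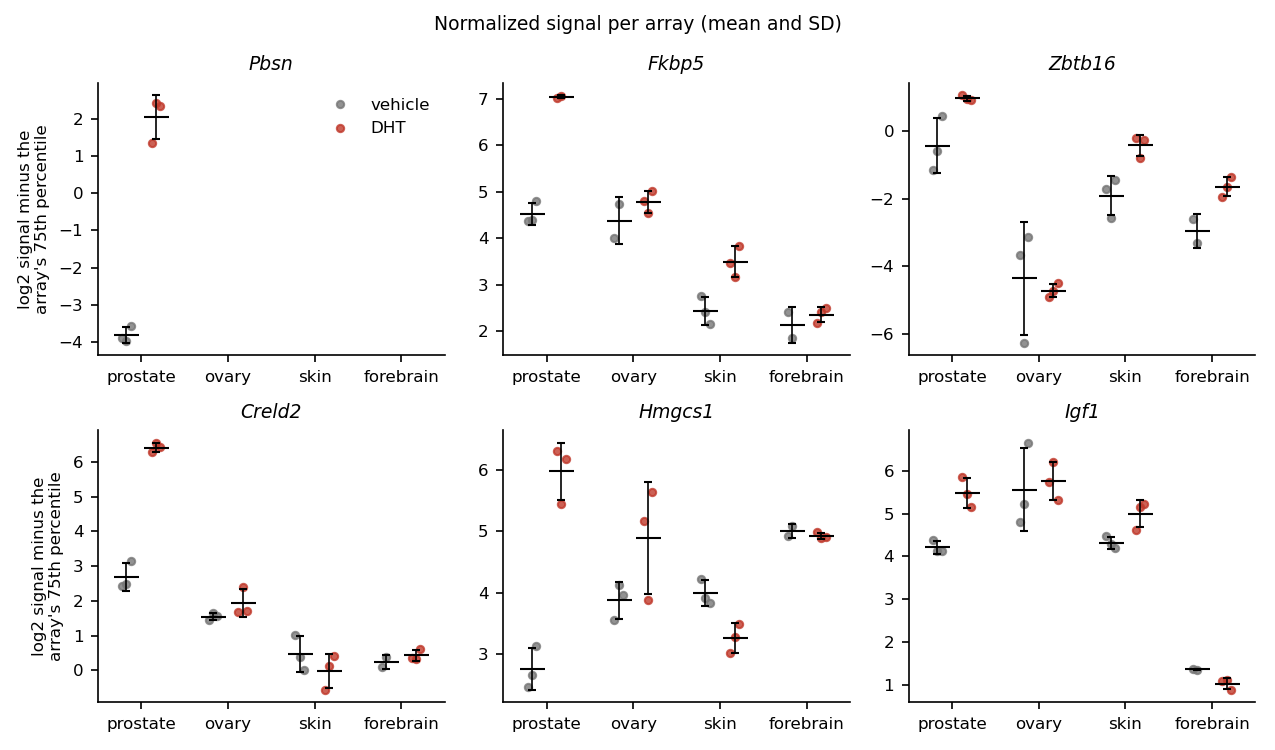
Normalized log2 signal (vertical axis, log2 difference from the 75th percentile of the array) of 6 genes on each array, by tissue and treatment, with the mean and SD of each group. Pbsn, tested in prostate alone, rose from a mean of -3.81 to 2.04, and the prostate means of Fkbp5 were 4.52 with vehicle and 7.05 with DHT.

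Cholesterol synthesis and protein folding rose together in prostate. Of 22 measured cholesterol genes, 18 rose and 0 fell over all genes tested, and 19 rose when adjusted over the list alone. Mvd rose by 2.45 ± 0.21 log2 units, Acat2 by 2.44 ± 0.21 and Idi1, an isomerase of the pathway, by 3.09 ± 0.28. Of 21 genes of endoplasmic reticulum folding and the unfolded protein response, 15 rose, among them Creld2 (3.73 ± 0.23), the chaperones Calr (2.58 ± 0.18) and Hsp90b1 (1.78 ± 0.15) and the disulfide isomerase Pdia4 (2.33 ± 0.20). The other 2 genes called in that list fell, the stress-induced genes Trib3 (-1.65) and Atf3 (-1.62). Of 16 fatty acid synthesis genes 6 rose, among them Scd2 (2.83 ± 0.16), Acsl3 (1.33 ± 0.16), Elovl6 (1.56 ± 0.22) and Mlxipl (1.58 ± 0.25). The lists passed camera at adjusted p = 5.24e-12 for cholesterol, 4.45e-07 for folding and 3.85e-04 for fatty acids. With an estimated correlation the unadjusted p was 0.0907, 0.0347 and 0.105, and the adjusted p was 0.612 for each. With fry the adjusted p was 0.0185, 0.00181 and 0.0234.

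Adipocyte markers also rose in prostate, 5 of 10 measured members over all genes and 9 adjusted over the list alone. Fabp4 rose by 1.30 ± 0.18 log2 units, Cd36 by 1.18 ± 0.17, Cidec by 1.59 ± 0.24 and Adipoq by 1.43 ± 0.22 (list adjusted p = 9.97e-06, p = 0.0820 with an estimated correlation). Fry gave that list an adjusted p of 0.0200. Its mean level was 0.29 ± 0.23 (SD) on vehicle and 1.28 ± 0.24 on DHT arrays.

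Cell cycle and immediate early genes lay lower in prostate with DHT, as groups. The cell cycle list had a median log2 fold change of -0.70 over 15 genes, of which 0 passed over all genes tested (limma, 8 at an unadjusted p under 0.05) and 8 were lower adjusted over the list alone, among them Rrm2 (-2.22 ± 0.57), Ccna2 (-2.26 ± 0.64), Ccnb1 (-1.50 ± 0.39) and Ccnb2 (-1.46 ± 0.43). Of 14 immediate early genes, Btg2 (-1.88 ± 0.15), Junb (-1.67 ± 0.15) and Jun (-1.10 ± 0.20) fell and Nr4a1 rose (1.15 ± 0.26). Of 21 genes known to rise after castration, Gstm1 (-2.04 ± 0.31), Plau (-1.55 ± 0.29), Tgfbr2 (-0.78 ± 0.16, 2 vehicle arrays) and Tgfb3 (-0.92 ± 0.22) fell and 0 rose. The adjusted p of the lists was 8.87e-05 for cell cycle, 0.00560 for immediate early genes and 0.0240 for castration, and with an estimated correlation p was 0.1699, 0.0248 and 0.0795, and after adjustment 0.634, 0.612 and 0.612, so that no call was kept. With fry the adjusted p was 0.0747 for cell cycle, 0.00181 for immediate early genes and 0.0581 for castration. The castration list was not called in 2 of the 6 fits with 1 array left out (highest adjusted p = 0.112).

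Prostate secretory products and polyamine enzymes had single strong members but no call as lists with camera (adjusted p = 0.0824 and 0.162). With fry, which does not compare a list with the other genes, both passed (adjusted p = 0.0305 and 0.0200). Among 11 secretory genes Pbsn, Klk1c9 (1.42 ± 0.31) and Scgb2a1 rose, the last from a level not well above background on vehicle arrays, and the ribonuclease gene Rnase1 fell (-2.74 ± 0.27, well above background on 1 of 3 DHT arrays). Among 8 polyamine genes Odc1, Srm (2.40 ± 0.16) and Sms (1.89 ± 0.23), both synthases of the pathway, rose. Apart from Pbsn, Odc1 and Srm these members were named after their values had been seen.

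Over the whole prostate array, 2288 of 23738 genes passed, 1194 higher and 1094 lower with DHT, of which 730 and 704 changed at least 2-fold (limma). Among the 6500 genes with a symbol, 394 rose and 353 fell. In 35.8% of the genes the groups did not overlap, against 10% by chance. The number of genes changed by DHT in prostate was 702 without vehicle array 1, 692 without vehicle array 2, 1188, 574 and 991 without DHT arrays 1, 2 and 3, and 2746 without vehicle array 3. It was 648 with normexp, 619 with no filter on dim probes and 5357 with array weights. Prostate vehicle array 3 had a log2 interquartile range of 5.23, against 6.80 and 6.71 on the other vehicle arrays. It also had 1531 outlier spots, against 2 to 273 on the other prostate arrays. This array shared a slide with ovary vehicle array 3 and with the forebrain array left out by the authors.

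**Figure D3:**
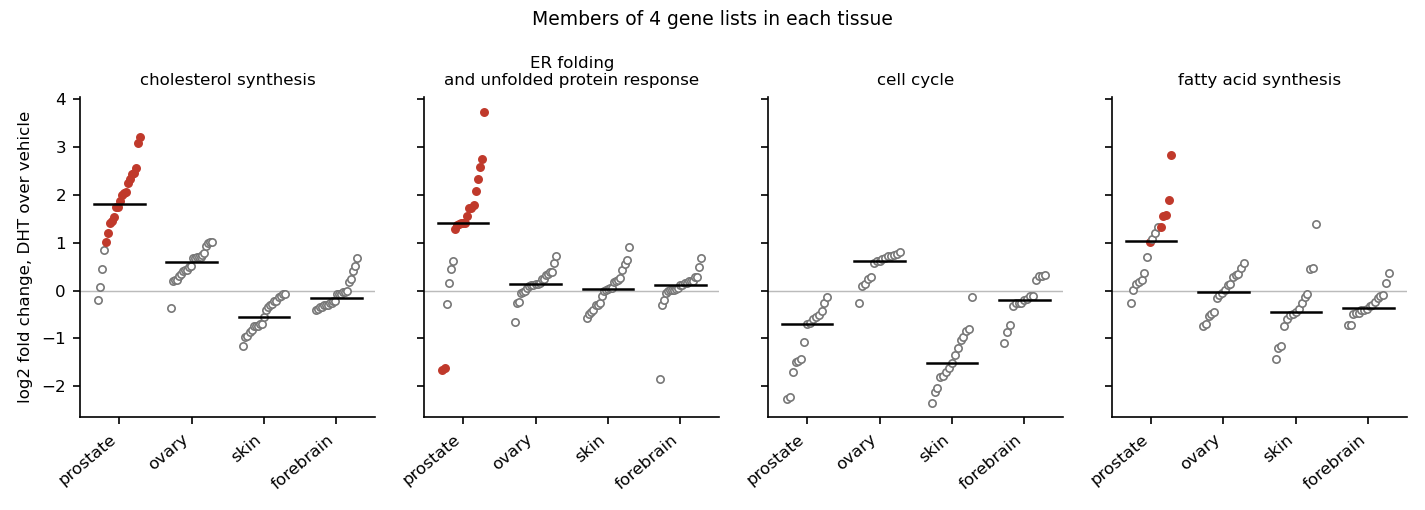
Log2 fold change, DHT over vehicle (vertical axis), of each measured member of 4 gene lists in each tissue, with the median as a line and members past an adjusted p of 0.05 filled. Filled points occur in prostate alone, where 18 of 22 cholesterol genes rose, and the medians of the cell cycle list were -0.70 in prostate, 0.62 in ovary, -1.51 in skin and -0.20 in forebrain.

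In ovary, cholesterol synthesis and cell cycle genes lay higher with DHT as groups, while 0 single genes passed the test. Of 22 cholesterol genes 21 had a positive log2 fold change (median 0.60), with Acat2 at 0.70 ± 0.22, Msmo1 at 0.94 ± 0.33, Mvd at 0.99 ± 0.37 and Fdps at 0.68 ± 0.26. Of 15 cell cycle genes 14 were positive (median 0.62), with Cdc20 at 0.80 ± 0.30, Ccnd1 at 0.65 ± 0.25, Tyms at 0.68 ± 0.26 and Rrm2 at 0.72 ± 0.29. Other probes differed for some members, with -0.13 for Rrm2, -0.38 and -0.80 against 0.27 for Rrm1, and 0.02 against 0.62 for Ccna2. None of these members passed, over all genes or adjusted over the list alone, and the lists passed at adjusted p = 1.38e-12 and 4.28e-09 (p = 0.0424 and 0.0228 with an estimated correlation, where both calls were lost at an adjusted p of 0.594). With fry the adjusted p was 0.404 for both lists. Ovary vehicle arrays 1 and 3 had 96.5% and 97.0% of probes well above background and a log2 interquartile range of 3.79 and 3.21, against 6.15 on vehicle array 2. Leaving out both arrays set 1 vehicle array against 3 DHT arrays, with all spread from the DHT arrays, so that the values then obtained do not uphold the calls. The cholesterol list had then a median of 0.58 and an adjusted p of 2.38e-05 (p = 0.241 with an estimated correlation), and the cell cycle list a median of 0.50 and an adjusted p of 5.09e-04 (p = 0.0488). The median of all genes moved from -0.23 to 0.02, so that both lists lay closer to the other genes than with all arrays.

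Of the other 6 ovary lists with a call, 0 had one with 1 vehicle array left. They were protein folding (adjusted p = 0.00239 with and 0.337 without both), polyamines (0.0387 and 0.361), ribosome biogenesis (2.07e-05 and 0.809), ovarian steroidogenesis (0.0182 and 0.189), shared steroid receptor targets (0.0462 and 0.238) and fibroblast genes (0.0462 and 0.112). The unadjusted p with an estimated correlation was 0.1702, 0.0509, 0.1702, 0.0883, 0.164 and 0.197. With 1 array left out, the camera call of steroid targets ended in 4 of 6 fits (highest adjusted p = 0.234). Those of fibroblast genes (0.219) and steroidogenesis (0.207) ended in 3, those of polyamines (0.175) and folding (0.0955) in 2, and that of ribosome biogenesis in 0. The medians with all arrays and with 1 vehicle array were 0.14 and 0.16 for folding, 0.14 and 0.05 for polyamines, 0.27 and -0.02 for ribosome biogenesis, 0.20 and 0.32 for steroidogenesis, 0.15 and 0.18 for steroid targets and 0.16 and 0.31 for fibroblast genes. Against the median of all genes, -0.23 with all arrays and 0.02 with 1 vehicle array, each of these lists lay closer to the other genes in the second case. How much of each shift came from the compressed arrays stays open with 1 vehicle array. With quantile normalization the direction of the steroidogenesis list turned (adjusted p = 0.869). The run with 1 vehicle array had new calls of lists lying lower, for adipocyte (median -0.64, adjusted p = 0.00331), ovulatory response (-0.57, 0.0375) and immediate early genes (-0.95, 8.29e-10) (p = 0.237, 0.242 and 0.0324 with an estimated correlation).

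Of the 29400 ovary genes, 0 passed (limma, lowest adjusted p = 0.119) and 3076 had an unadjusted p under 0.05, 78 higher and 2998 lower with DHT. The median log2 fold change of all genes was -0.23, and 0.09 with quantile normalization. With quantile normalization 38.8% of the genes at an unadjusted p under 0.05 were lower, against 97.5%. Fkbp5 (0.41 ± 0.35), Sgk1 (0.35 ± 0.32), Tsc22d3 (0.33 ± 0.36), Clu (-0.09 ± 0.34), Odc1 (0.39 ± 0.32), Igf1 (0.20 ± 0.54) and Zbtb16 (-0.36 ± 0.81, with -3.07 on another probe) did not pass. The 3 other probes of Igf1 had negative values. With 1 vehicle array left after the compressed arrays were taken out, the values of Clu (0.24) and Odc1 (-0.01) had the opposite sign and that of Fkbp5 was 0.05. With quantile normalization Zbtb16 had 1.099 and Fkbp5 0.13. Zbtb16 was well above background on 2 of 3 vehicle arrays, not on the uncompressed one, so that no fold is given against that array alone. Without vehicle array 2 the number of genes changed by DHT in ovary was 7578, with both compressed arrays as the whole vehicle group, and without both compressed arrays it was 0 (1262 at an unadjusted p under 0.05).

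In skin, cell cycle genes lay lower with DHT and targets shared by steroid receptors higher, as groups, while the list of androgen response genes did not shift (adjusted p = 0.796, 11 of 26 genes higher). All 15 cell cycle genes had a negative log2 fold change (median -1.51), 11 at an unadjusted p under 0.05, with Aurka at -1.51 ± 0.32, Birc5 at -1.78 ± 0.49, Rrm1 at -0.79 ± 0.24 and Aurkb at -2.34 ± 0.77, and 1 (Aurka) passed adjusted over the list alone. Among the 17 steroid receptor targets, Pdk4, a kinase that restrains glucose oxidation, had 3.56 ± 0.75 and Zbtb16 1.48 ± 0.37, both passing adjusted over the list alone, with Fkbp5 at 1.05 ± 0.30 and Ddit4 at -0.86 ± 0.30. The adjusted p was 5.56e-12 for cell cycle and 0.0222 for steroid targets (p = 0.0757 and 0.0405 with an estimated correlation, where both calls were lost at an adjusted p of 0.502). With fry the adjusted p was 0.393 for both lists. The steroid target list was not called in 2 of the 6 fits with 1 array left out.

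Lipid and hair genes lay lower in DHT skin and muscle genes higher, as groups. Cholesterol synthesis had a median of -0.55 (21 of 21 negative, adjusted p = 5.15e-06), with Acat2 at -0.96 ± 0.34 and Hmgcs1 at -0.73 ± 0.27, and fatty acid synthesis one of -0.44 (adjusted p = 0.00868), with Fads1 at -1.44 ± 0.47 and Elovl6 at -1.20 ± 0.44. The sebaceous list (median -0.40, adjusted p = 0.0168), ribosome biogenesis (-0.33, 2.98e-04) and the list of prostate secretory products (-1.07, 0.00440) were also lower. In the last list Scgb1d2 (-3.95 ± 1.13), Andpro (-3.33 ± 0.97) and Scgb1d4 (-4.03 ± 1.21) passed adjusted over the list alone. With an estimated correlation p was 0.147, 0.0358, 0.0633, 0.217 and 0.0544 for these lists in that order, and 0 calls were kept after adjustment. With 1 array left out, the call of the secretory products ended in 3 of 6 fits (highest adjusted p = 0.181), that of the sebaceous list in 2 (0.171), and those of fatty acids (0.129) and muscle (0.145) in 1 each. Hair follicle genes had a median of -2.21 (13 of 14 negative, adjusted p = 1.12e-04, p = 0.244 with an estimated correlation), among them Krt36 (-1.23 ± 0.52), Lef1 (-2.41 ± 1.17), Dsg4 (-2.04 ± 1.03) and Msx2 (-2.46 ± 1.26). The mean level of the hair list was -2.33 on DHT array 1 and between 1.34 and 2.73 on the other arrays. Cell cycle genes were lowest on the same array (-1.34, against -0.12 to 1.38 on the others). Skeletal muscle genes had a median of 4.18 (adjusted p = 0.00684, p = 0.321 with an estimated correlation), with a mean level of -1.78 on vehicle array 1 and between 8.18 and 10.6 on the other arrays.

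Of the 24122 skin genes, 0 passed (limma, lowest adjusted p = 0.752) and 1192 had an unadjusted p under 0.05, against 1206 by chance. The skin arrays were the dimmest, with a 75th percentile of signal of 55.6 (DHT array 1) to 379 (vehicle array 1). On all other arrays it was 486 or more. Lists of low level thus lay near background in skin, such as prostate secretory products (-3.62 ± 0.45 on vehicle and -4.52 ± 0.79 on DHT arrays). Igf1 (0.68 ± 0.27), Tsc22d3 (0.45 ± 0.25), Odc1 (-0.56 ± 0.32), Clu (0.36 ± 0.33) and Sgk1 (0.04 ± 0.40) did not pass. The sign of Sgk1 turned when single arrays were left out.

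**Figure D4:**
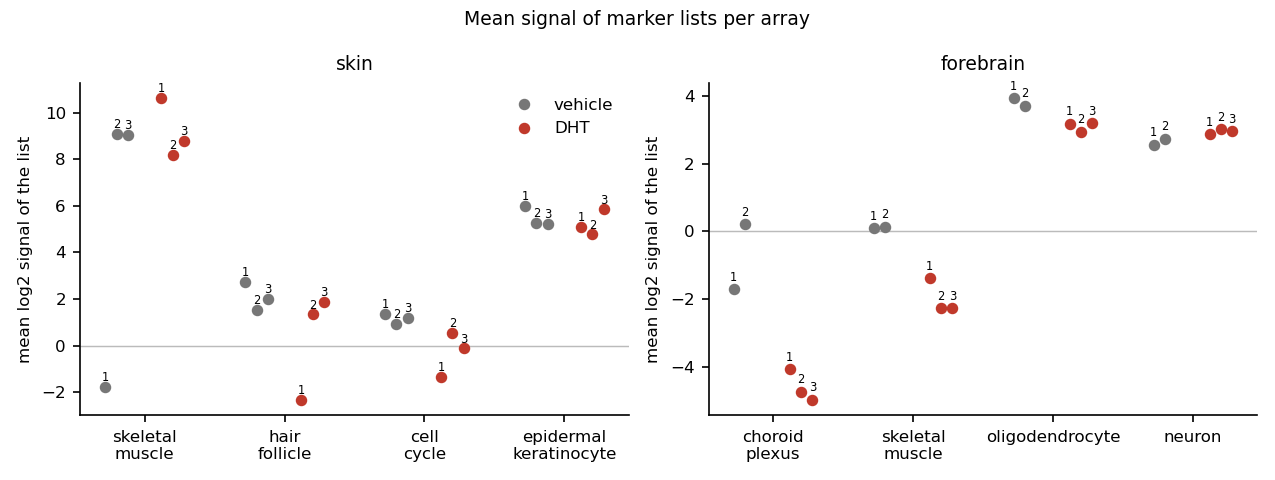
Mean log2 signal (vertical axis, log2 difference from the 75th percentile of the array) of marker lists on each array of skin (left) and forebrain (right), with replicate numbers above the points. In skin, muscle genes lay at -1.78 on vehicle array 1 and hair follicle genes at -2.33 on DHT array 1. In forebrain, choroid plexus genes lay at -1.70 and 0.21 on vehicle arrays and at -4.06, -4.73 and -4.97 on DHT arrays.

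In forebrain, the lists with the largest shifts were markers of choroid plexus, the secretory lining of the ventricles, and of skeletal muscle, both lower with DHT. The plexus list had a median log2 fold change of -3.02 over 8 genes, 6 of which were lower adjusted over the list alone, with Ttr, the thyroid hormone carrier of cerebrospinal fluid, at -8.70 ± 0.73, Sostdc1 at -6.84 ± 0.57, Aqp1 at -2.54 ± 0.32 and Clic6 at -4.54 ± 0.95 (well above background on 1 of 3 DHT arrays). Of 14 muscle genes 12 were lower and 2 higher (Cox6a2 0.56 and Pvalb 0.63) adjusted over the list alone, with Myh4 at -4.75 ± 0.36, Tnni2 at -2.72 ± 0.27, Actn3 at -2.91 ± 0.30 and Myl11 at -2.49 ± 0.29. Both lists had an adjusted p of 4.51e-05 (p = 0.151 for plexus and 0.106 for muscle with an estimated correlation). The mean muscle level was 0.09 and 0.14 on the vehicle arrays and -1.38, -2.28 and -2.26 on the DHT arrays.

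Glial and immune markers were also lower in DHT forebrain, and neuronal markers were slightly higher. All 12 oligodendrocyte genes were negative (median -0.61), with Sox10 at -0.88 ± 0.16 and Mobp at -0.89 ± 0.20, and so were all 12 astrocyte genes (median -0.43), with Ntsr2 at -1.16 ± 0.24. Neuronal genes had a median of 0.23 (13 of 14 positive), with Nefm at 0.62 ± 0.12, Nefl at 0.77 ± 0.15 and Gad1, which makes GABA, at 0.999 ± 0.213. The adjusted p was 1.15e-04 for oligodendrocyte, 0.00330 for astrocyte and 0.00499 for neuronal genes, and 0.00152 for interferon response (median -0.76), 0.00746 for immune cell (-0.48), 0.00799 for fatty acid synthesis (-0.35), 0.0130 for fibroblast (-0.45), 0.0217 for endothelial (-0.56), 0.0257 for castration (-0.30) and 0.0393 for hair follicle genes (-0.50). With an estimated correlation p was 0.113, 0.171, 0.0850, 0.147, 0.104, 0.0446, 0.0572, 0.269, 0.0721 and 0.155 in that order, and 0 calls were kept after adjustment. With 1 array left out, the endothelial call ended in 2 of 5 fits (highest adjusted p = 0.207), those of castration (0.1095) and hair follicle genes (0.0569) in 2, and those of fibroblast (0.0529) and fatty acid genes (0.0551) in 1. The castration list lost its call with quantile normalization (adjusted p = 0.154).

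Of the 26361 forebrain genes, 0 passed (limma, lowest adjusted p = 0.0715) and 7234 had an unadjusted p under 0.05, 3360 higher and 3874 lower, against 1318 by chance. In 47.3% of the genes the groups did not overlap, against 20% by chance for 2 arrays against 3. Clu (-0.73 ± 0.14), Zbtb16 (1.31 ± 0.28), Sgk1 (-0.61 ± 0.21), Igf1 (-0.34 ± 0.13), Fkbp5 (0.22 ± 0.21), Tsc22d3 (-0.25 ± 0.18) and Odc1 (-0.13 ± 0.12) did not pass, with adjusted p from 0.0728 to 0.533. Tsc22d3 turned sign with the array left out by the authors (0.12), and Fkbp5 and Tsc22d3 without vehicle array 2. In other fits the number of genes changed by DHT in forebrain was 3146 with a variance prior with trend and robust estimation, 1536 with genes well above background on all arrays, 500 with normexp, 1 without DHT array 1 and 49 without vehicle array 1, where a lone vehicle array was assumed to vary like the others.

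The effect of DHT differed between tissues in 1012 of 20751 genes (limma moderated F test), and the 10 clearest named genes had their largest effect in prostate. Fut4, a fucosyltransferase gene, had 2.81 ± 0.18 in prostate, -0.11 in ovary, -0.40 in skin and -0.92 in forebrain (adjusted p = 4.08e-07). In prostate, ovary, skin and forebrain, Acat2 had 2.44, 0.70, -0.96 and -0.28 and Hmgcs1 3.21, 1.015, -0.73 and -0.09. In the same order Tmem97 had 1.71, 0.41, -0.69 and -0.20 and Scd2 2.83, -0.09, -1.15 and -0.71. Outside prostate none of the values of Acat2, Hmgcs1, Tmem97 and Scd2 passed (limma, lowest adjusted p = 0.077). Creld2, Srm, Calr and the potassium channel gene Kcnh2 had between 2.40 and 3.73 in prostate and between -0.50 and 0.38 in the other tissues. Nfkb2, a subunit of the transcription factor NF-kB, had -2 in prostate and 0.23, 0.14 and -0.53 in ovary, skin and forebrain. In pairs of tissues, the effect in prostate differed from that in ovary in 563 genes, in skin in 1091 and in forebrain in 688, and the other pairs differed in 12 (ovary and skin), 4 (ovary and forebrain) and 28 genes (skin and forebrain). Ovary alone came from intact females, the other tissues from castrated males. Differences that involve ovary therefore do not separate tissue from sex and castration, and they include both compressed ovary vehicle arrays.

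As lists, cholesterol genes had a higher effect in prostate than in ovary (adjusted p = 6e-06), skin (4.35e-18) and forebrain (8.96e-14), and folding genes likewise (9.85e-07, 1.1e-07 and 5.12e-07). Cell cycle genes had a higher effect in ovary than in skin (8.96e-14) and in prostate (7.31e-11). The limits of sex, castration and compressed arrays hold for ovary here too. These camera tests had no slide block, although arrays of a slide shared deviations. With an estimated correlation the unadjusted p was 0.0951, 0.00507 and 0.0125 for cholesterol, 0.0243, 0.0163 and 0.0214 for folding and 0.0109 and 0.0215 for cell cycle, and 0 of the 114 tests of list differences passed after adjustment. The number of genes whose DHT effect differs between tissues was 332 and 1926 without the slides of vehicle replicates 1 and 2, and 209, 338 and 125 without those of DHT replicates 1, 2 and 3. It was 664 with quantile normalization, 326 with normexp, 579 without the slide block and 303 with the forebrain array left out by the authors.

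On average over the 4 tissues, 44 genes rose and 22 fell. Fkbp5 rose by 1.05 ± 0.15 log2 units on average (adjusted p = 0.00823), with 2.50 in prostate, 1.05 in skin, 0.41 in ovary (0.13 there with quantile normalization) and 0.22 in forebrain. The other named rises were Creld2 (0.95 ± 0.17), Kcnh2 (0.89 ± 0.17), the cholesterol genes Fdft1 (0.82 ± 0.16) and Mvd (0.71 ± 0.15), Usp2 (0.82 ± 0.17), Syngr1 (0.80 ± 0.15), the cargo receptor Lman1 (0.72 ± 0.12), Calr (0.72 ± 0.14) and Herpud1 (0.62 ± 0.13). The named falls were Foxq1, a transcription factor gene (-1.08 ± 0.14, adjusted p = 0.00374), Hsd11b2, which inactivates glucocorticoids (-1.40 ± 0.29, 0.0486), Prr5l (-0.53 ± 0.10, 0.0327) and Sostdc1 (-1.83 ± 0.35, 0.0356), whose fall lay in forebrain (-6.77). For all of them but Hsd11b2 (adjusted p = 0.595) the effect also differed between tissues. The number of genes changed by DHT on average over the 4 tissues was 0 without the slide of DHT replicate 2 or that of DHT replicate 3, 1 without DHT replicate 1 and 129 without vehicle replicate 3. It was 469 with normexp, 324 without the slide block, 21 with genes kept in at least 1 tissue and 7 with the forebrain array left out by the authors.

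In the fits of single tissues the overlap of changed genes between tissues was 0 with adjusted p, since prostate alone had any. In the fit of all arrays over the 20751 genes kept in all tissues, ovary, skin and forebrain had 38, 4 and 33 calls, and Foxq1 was lower in both prostate (adjusted p = 4.67e-04) and ovary (0.00229), so that the overlap there was not 0. The ovary calls of that fit include both compressed vehicle arrays. In the fit of ovary alone, which includes them too, genes called higher in prostate had a median log2 fold change of 0.06. All genes there had -0.23 (camera p = 2.32e-10, and 0.0371 with an estimated correlation). Genes called lower in prostate, and both sets in skin and forebrain, had a camera p of 0.0583 or more. At an unadjusted p under 0.01, 231 genes moved the same way in at least 2 tissues. No number expected by chance was computed for this total, and independent lists would share part of it. Prostate and forebrain shared 91 higher genes against 63.2 expected from independent lists (Fisher's exact test, two-sided, adjusted p = 0.00241 over 12 tests), skin and forebrain 13 lower genes against 3.88 (0.00121), and prostate and skin 10 lower genes against 3.95 (0.0179). Ovary and forebrain shared 8 lower genes, fewer than the 19.2 expected (0.0179), and ovary and skin shared 1 higher gene against 0.0149 (0.0355). The 7 other tests did not pass. Among them, prostate and forebrain shared 81 lower genes against 81.4 expected, and prostate and ovary 20 lower genes against 13.6. Fisher's exact test takes genes as independent, which they are not, so that these p-values may be too small. Across genes, which are not independent replicates, the fold changes of prostate and ovary had a Pearson correlation of 0.157 (Spearman 0.178) and those of ovary and skin one of -0.2 (-0.219). For the pairs with more shared genes than expected it was -0.0135 (-0.0314) for prostate and forebrain, -0.0391 (-0.0574) for skin and forebrain and 0.0765 (0.0772) for prostate and skin. For ovary and forebrain it was -0.0247 (-0.0169). Arrays of different tissues on one slide shared part of their deviations, with a median correlation of 0.294 for forebrain and prostate, 0.219 for prostate and skin and 0.147 for forebrain and skin. For arrays on different slides it was -0.169, -0.0902 and -0.104. Ovary shared less on one slide, with 0.132 for prostate, 0.0635 for forebrain and 0.0293 for skin. Each slide held 1 treatment, so that genes shared through slide and through DHT cannot be told apart.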

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

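Before the data were examined, the tests by regrouping of the arrays had been fixed, and the bounds for the ovary run without both compressed arrays and for the tissue difference of the clock genes were written before those tests ran though after the patterns had been noticed, whereas both forebrain tests, the test of DHT in ovary, the test of a shared collection time and the count of differing genes over splits of whole slides were chosen only after the result was seen.

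The effect of DHT on 1012 genes differed between prostate, ovary, skin and forebrain. Ovary came from intact females and the other tissues from castrated males, so tissue is not separated from sex and castration there. The adjusted p of that difference was 4.08e-07 for Fut4, 2.33e-05 for Acat2, 2.51e-05 for Creld2, 3.63e-05 for Srm, 5.67e-05 for Kcnh2, 1.28e-04 for Scd2, 1.47e-04 for Tmem97, 2.62e-04 for Hmgcs1, 2.82e-04 for Calr and 3.05e-04 for Nfkb2. Among the genes changed on average it was 0.00524 for Fkbp5, 0.00291 for Fdft1, 0.013 for Usp2, 0.0126 for Syngr1, 0.00213 for Lman1, 3.05e-04 for Mvd, 0.00665 for Herpud1, 9.13e-04 for Sostdc1, 0.0118 for Foxq1 and 0.00568 for Prr5l, so an average over tissues does not describe any of these genes alone. When treatment was redrawn within each tissue, 1 of 50 draws, the real one, gave 1012 genes, and the highest other gave 383. These draws break up the slides, whose arrays share deviations (median correlation 0.294 for forebrain and prostate), so that they do not exclude chance. Splits of whole slides keep them, and 1 of 10 gave 1012 genes and the highest other 9, which is too few splits for a share under 0.05.

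For single tissues the arrays allowed too few regroupings for a share under 0.05. In prostate 1 of 10 splits of the arrays gave 2288 genes, and the highest other gave 0. For the average over tissues 1 of 10 splits of the slides gave 66 genes, and the highest other gave 1. In ovary and in skin the real split gave 0 genes, and so did all 10 splits.

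Nearly all ovary genes at an unadjusted p under 0.05 were lower with DHT (97.46%). Vehicle arrays 1 and 3 of the ovary had compressed signal, and without both, with 1 vehicle array left, the percentage was 55.47, so most of this direction may come from those arrays and not from DHT. Whether DHT also lowered such genes was asked of the 9798 genes lower without vehicle array 2, and in 22.91% of them that array lay above all 3 DHT arrays and in 28% below them, with a median difference of DHT minus that array of 0.05. These values run against lower levels with DHT, but 1 array excludes nothing. The genes were chosen as lower on the same DHT arrays, so that the 25% expected by chance need not hold for them, and the question stays open. An earlier form of this test, with its bound written before it ran, had used the 2998 genes chosen with all arrays and gave 75.48%, just past the bound set for it and so in favour of an effect of DHT. It was replaced after that value had been seen, because vehicle array 2 had itself helped to choose those genes, and neither form decides.

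Choroid plexus and skeletal muscle genes were lower on the DHT forebrain arrays. Without Ttr and Sostdc1, the 2 genes with the largest falls, the plexus list still had a median log2 fold change of -2.615 over 6 genes. All 8 genes were already lower, and less plexus in the dissected DHT samples and an effect of DHT would both give this, so that the value does not decide between them. The exact two-sided permutation p of the mean plexus level was 0.1 with 10 splits, the smallest value that 2 arrays against 3 allow.

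Of the clock genes, Bhlhe40 (-1.79, adjusted p = 0.00868), Per3 (-1.64, 0.00541) and Nr1d1 (-1.22, 0.0410) were lower and Bmal1 (1.13, 0.0180) and Cry1 (0.84, 0.0441) higher in DHT prostate. These genes lie outside the rule for named genes, and were picked for weighing from several candidates after their values had been seen. In skin and forebrain 2 of 10 values had the sign seen in prostate, few enough to count against a collection time shared by the tissues under the bound set for it. None of the 10 had a call, and all skin values had the opposite sign. They are thus not 10 separate checks, and the count does not decide. That explanation was narrowed to a shared time after the values had been seen, and all 5 genes had the prostate sign in ovary, none with a call. The effect differed between tissues in 1 of 5 genes (Bhlhe40, adjusted p = 0.00268), which leaves open whether DHT acted on these genes in prostate alone.

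Forebrain vehicle array 3, which the authors left out, had 98.4% of probes well above background. Its signal was compressed, with a log2 interquartile range of 1.96 against 5.91 and 5.89 on the other vehicle arrays. Its correlation with the other forebrain arrays was 0.757 to 0.806. Its mean plexus level was -1.10 and its mean muscle level -0.03, against -1.70 and 0.21, and 0.09 and 0.14, on the other vehicle arrays. With such compression these levels do not bear on the lower plexus and muscle genes of the DHT arrays.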

How the results depend on the processing

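The normexp runs and the runs without the 2 compressed ovary arrays were chosen only after the result was seen. With the replicate number as a block, the number of genes changed by DHT in prostate was 0, against 2288, and numbers did not pair samples (same-number correlations of -0.4293 to 0.01171). It was 648 with normexp, 619 with no filter on dim probes, 5357 with array weights, and 574 to 2746 with 1 array left out. Clu in prostate was -0.10 with quantile normalization. With quantile normalization the number of genes changed by DHT in ovary was 15, and it was 83 with array weights, 365 with all arrays in 1 fit, 390 with slide as a block there, and 0 to 7578 with 1 array left out. The fits of all arrays counted here used the genes kept in the tissue named, 29400 in ovary. The 38 ovary calls given in the Results came from the 20751 genes kept in all tissues. Zbtb16 in ovary was 1.099 with quantile normalization, 1.54 without both compressed arrays (no exact fold, since the 1 vehicle array left was not well above background), and -2.79 to 0.25 with 1 array left out. The low end of that range, -2.79, cannot come from the Zbtb16 probe fitted with all arrays. That probe had levels of -3.671, -6.255 and -3.14 on ovary vehicle arrays and -4.9, -4.739 and -4.498 on ovary DHT arrays. Another Zbtb16 probe had -3.075 in ovary with all arrays. The brightest probe of a gene was chosen anew in each fit, so that the range of Zbtb16 mixes probes and is not that of 1 probe. Without both compressed arrays, Clu in ovary was 0.24 and Odc1 in ovary -0.00527. Leaving out 1 array gave -0.00973 to 0.60 for Tsc22d3 in ovary, -0.30 to 0.18 for Clu and -0.19 to 0.75 for Igf1 in ovary. The list ovarian steroidogenesis in ovary had an adjusted p of 0.869 with quantile normalization. With all arrays in 1 fit the number of genes changed by DHT in skin was 4, and it was also 4 with slide as a block. With 1 array left out, Sgk1 in skin was -0.25 to 0.34. With normexp the number of genes changed by DHT in forebrain was 500, and it was 1536 with probes above background on all arrays, 3146 with trend and robust estimation, 38 with all arrays in 1 fit, 40 with slide as a block, and 0 to 49 with 1 array left out. Fkbp5 in forebrain was -0.0478 to 0.50, and Tsc22d3 in forebrain -0.50 to 0.0122, or 0.12 with the array left out by the authors. The gene list shifts in each tissue were 0 with estimated correlation, against 36. The overlap of changed genes between tissues was 231 at an unadjusted p under 0.01, a total that includes genes shared by chance. The number of genes whose DHT effect differs between tissues was 664 with quantile normalization, 326 with normexp, 579 with no slide block, 303 with the forebrain array left out by the authors, and 125 to 1926 with 1 slide left out. The number of genes changed by DHT on average over the 4 tissues was 469 with normexp, 21 with genes kept in at least 1 tissue, 324 with no slide block, 14 with the replicate block, 7 with the forebrain array left out by the authors, and 0 to 129 with 1 slide left out. Among values of the genes reported 757 stayed the same, 161 weakened, 11 strengthened and 17 reversed. These totals pool genes with and without a call, and only a gene with a call could weaken. Of the values of called genes, 81 of 272 weakened with 1 array or slide left out and 23 of 23 with the replicate block. With the replicate block and slide as a random block 12 of 24 weakened, and 13 of 24 with the forebrain array left out by the authors. With array weights 0 of 23 did. The cause was not tested for any of these.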

Other observations

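The values below, and any test of them, were chosen only after the result was seen. Zbtb16, a transcription factor gene induced by steroid hormones, had a log2 fold change of 1.40 ± 0.39 in prostate, 1.48 ± 0.37 in skin and 1.31 ± 0.28 in forebrain (SE), with 0 calls over all genes. In ovary it was -0.36 ± 0.81 with all arrays and -3.07 on another probe. In prostate the growth factor genes Igf1 (1.28 ± 0.22) and Igf2 (1.25) rose, with 1.21, 0.43 and 0.32 on the other probes of Igf1, and so did Far1 (1.99) and Pparg (1.16), which belong to the list of sebaceous and skin lipid genes. In forebrain the neuropeptide genes Tac1 (-1.58), Gnrh1 (-1.92), Gal (-1.88) and Penk (-1.04, but 0.43 on another probe) had negative values and Sst (0.48) and Crh (1.12) positive ones, none past the test over all genes, and of the 19 genes of their list 6 were higher and 13 lower (list adjusted p = 0.137). Without the compressed ovary arrays the immediate early genes had a median of -0.95 against 1 vehicle array, and one of -0.33 with all arrays (adjusted p = 0.614), so that the first value may be that of 1 sample.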
